A study of Bactrocera oleae with 12 samples.

How the data were processed

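RNA of whole female olive fruit flies (Bactrocera oleae, a pest whose larvae feed in olives) was hybridised to 12 Agilent 2-colour arrays of a custom design. Each RNA sample came from a pool of 10 females aged 1 to 3 days, per the labels. AN12 and AN14 came from orchards on Crete treated intensively with pyrethroids and were collected in 2012 and 2014, and FOK14 came in 2014 from a region of central Greece with very little insecticide use. HYB and LAB are named in the labels without a description and are used here as names. The arrays fall into 3 groups of 4, AN12 against HYB, AN14 against LAB and AN14 against FOK14. Per the labels, the population named first was labelled with Cy5 and the other with Cy3 on each array, so no dyes were exchanged. A dye effect of a gene therefore cannot be separated from a direct comparison. It cancels in the difference between the 2 AN14 groups if it is equal in both. The labels call the replicates of LAB, AN12, AN14 and FOK14 biological; the same is not said of HYB, for which p-values measure the spread between arrays.

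Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 10.5 and limma with no version. The deposited scanner files hold the intensity of each spot and its local background in both channels, with no background subtracted from the columns used. The deposited value table holds log10 ratios of Cy5 over Cy3, which equalled the scanner software's background-subtracted and dye-normalised log ratio in 62919 of 62919 spots of each array, within a relative tolerance of 0.006. Its scale and direction were thus known, each column's median was 0, and it had no further centring. Between 15.2% and 20.9% of the values per array were exactly 0. The other columns used are the flags of the authors' scanner software for spots well above background, saturated or non-uniform.

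The design fixed before the data were examined named mean spot signals, but the scanner files give median signals, so medians were used throughout. Background was corrected with normexp (offset 50), fitted on all spots, and log2 ratios were normalised within each array by loess, with control and non-uniform spots at weight 0. Spots of a probe were averaged, and a probe was kept where either channel was well above background on at least 4 arrays, which left 43326 of 59976 probes. Of 20516 targets on the array, 16061 were tested, each through its brightest probe; 13388 of them had more than 1 tested probe. Another target was left out for missing values. The target names are those of the array design: contigs, parts of contigs and reverse complements of contigs, 223 sequence accessions, 13 intervals of a sequence record and 15 cytochrome P450 names. None of the targets matched the 16948 genes of the reference table (assembly idBacOlea1) by identifier, so contigs keep their identifiers and have no gene name or genome position here. Only identifiers were compared, so this does not show that the targets lack counterparts among these genes. The fixed design also named a match of probe sequences to reference transcripts, which is not reported here.

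All 12 arrays entered a single limma fit (limma 3.58.1, R 4.3.3) with a coefficient per group, tested against 0 with lmFit and eBayes and adjusted by Benjamini-Hochberg over all targets. A target was called at an adjusted p below 0.05 and a log2 ratio of at least 1 either way. FOK14 over LAB was the contrast of AN14 against LAB minus AN14 against FOK14, which equals that ratio if AN14 was alike in both groups. In the values after ±, the error is the SD of 4 arrays. Where a target was not well above background on any array of a population, a fold is given as a bound. For this bound the brighter mean was set against the lowest signal well above background, or the dim spot's own signal where higher, per channel after loess and Aquantile; such bounds are open to dye bias. For FOK14 over LAB, the bound was taken from the ratios to AN14, with the dim signal raised to this floor.

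The 20 gene lists fixed before the data were examined are patterns on gene names. Only the cytochrome P450 list had targets, after the prefix bo of the array's names was removed, which is a departure from the pattern as written; the other 19 lists matched no target. The list's shift was tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it; as 1 list was tested, its p needs no adjustment over lists. The rule for named genes took, per comparison, the 10 described targets with the largest called ratio each way and the same sign on all arrays, up to 2 called members of each list each way, described targets called alike in all 3 comparisons, the 5 largest each way for FOK14 over LAB, and the sodium channel and acetylcholinesterase. No target could be assigned to these last genes. For targets without a gene name, at most 2 identifiers that rose and 2 that fell per comparison were named, those with the largest ratios among targets called with the same sign on all 4 arrays.

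Tested on simulated data for AN14 against LAB with 16062 targets, limma at the adjusted p alone recovered 94% of 50 targets changed by a log2 ratio of 1 and 100% of those changed by 1.5, 2 or 3. The changed targets were drawn from bright ones, and the noise was independent between arrays. For a change of 1 the mean ratio found was 0.96, and recovery at the full threshold was not scored. Of the 15862 unchanged targets in that simulated comparison, 21 passed the adjusted p and 1 passed the full threshold. Same-numbered arrays of the 2 AN14 groups deviated together: the correlations of their deviations from the group means were 0.405, 0.433, 0.194 and 0.386, each the highest of its array. The shared numbers were therefore taken to pair these arrays, and FOK14 over LAB was also fitted with the number as a block. The AN12 arrays lay on a slide of their own and all AN14 arrays on another, so slide and group cannot be told apart for AN12 against HYB in any comparison with the others.

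The alternatives were no background correction, a normexp offset of 1, median centring, the scanner software's log ratio, the deposited table, scaling between arrays, other filters, the mean of a target's probes, only the arrays compared, array weights, a separate-channel fit, the adjusted p alone, the replicate block, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.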

Results

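Transcript levels of whole females were compared between 5 olive fruit fly populations in a study of pyrethroid resistance. Each of the 3 comparisons had 4 arrays, and their number limits the precision. Median spot signals were 230 to 419 in Cy5 and 267 to 349 in Cy3, between 63.7% and 68.9% of the spots in Cy5 and 68.4% and 73.2% in Cy3 were well above background, and no spot was saturated. Log ratios correlated between arrays of a group with r from 0.814 to 0.904 for AN12 against HYB and from 0.809 to 0.882 for AN14 against FOK14. For AN14 against LAB they ranged from 0.656 to 0.904, and replicate 3 had the lowest values.

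The comparison of AN12 with HYB set flies from orchards under intensive pyrethroid use against the population HYB. Of the 15 P450 targets, 3 rose in AN12. CYP6A13, of a family with many insecticide-metabolising enzymes, was 5.03-fold higher in AN12 (log2 ratio 2.33 ± 0.21, SD, n = 4, limma adjusted p = 8.98e-10). CYP12A3, of a mitochondrial P450 family, was 2.82-fold higher (1.49 ± 0.60, SD, n = 4, limma adjusted p = 7.32e-05). CYP6P9, which shares its name with a pyrethroid-metabolising enzyme of the mosquito Anopheles funestus, was 2.11-fold higher (1.08 ± 0.07, SD, n = 4, limma adjusted p = 4.02e-08). All 3 were higher on 4 of 4 arrays.

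Another 7 P450 targets passed the adjusted p with log2 ratios under 1, among them CYP4D10 at 0.81, CYP6A14 at 0.63 and CYP9F2 at 0.52. The remaining 5, which include CYP18A1, the ecdysteroid 26-hydroxylase, at 0.22 and CYP4G1-2 at -0.27, did not pass. The other CYP4G1 target, CYP4G1-1, was among the 7 that passed and had the other sign, at 0.39. Adjusted over the list alone, 10 P450 targets passed, and the same 3 reached a log2 ratio of 1. The list lay above the other targets by camera, with a median log2 ratio of 0.45 (p = 0.00246 with the preset correlation and p = 0.035 with an estimated correlation). CYP6P9 fell below a log2 ratio of 1, to 0.99 after scaling between arrays and 0.91 as the mean of its probes, and lay at 1.72 with the scanner software's log ratio. The direction of all ratios of AN12 against HYB rests on the labels' dyes: an exchange of both RNAs before labelling would turn these rises into falls and stays open.

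Over all targets, 1318 were called between AN12 and HYB, 516 higher and 802 lower in AN12. The largest rises were those of contig04635, with a log2 ratio of 6.92 ± 1.00, and contig06783, with 6.88 ± 1.05 (SD, n = 4); in HYB these were well above background on 1 and 2 of 4 arrays. The largest falls were those of rc_contig12608, at -7.14 ± 0.09, and contig04482, at -6.61 ± 0.44, where AN12 was above background on 4 and 3 arrays. At the limma adjusted p alone 9256 targets passed, and with the scanner software's own log ratio 2074 were called, 959 higher and 1115 lower.

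**Figure D1:**
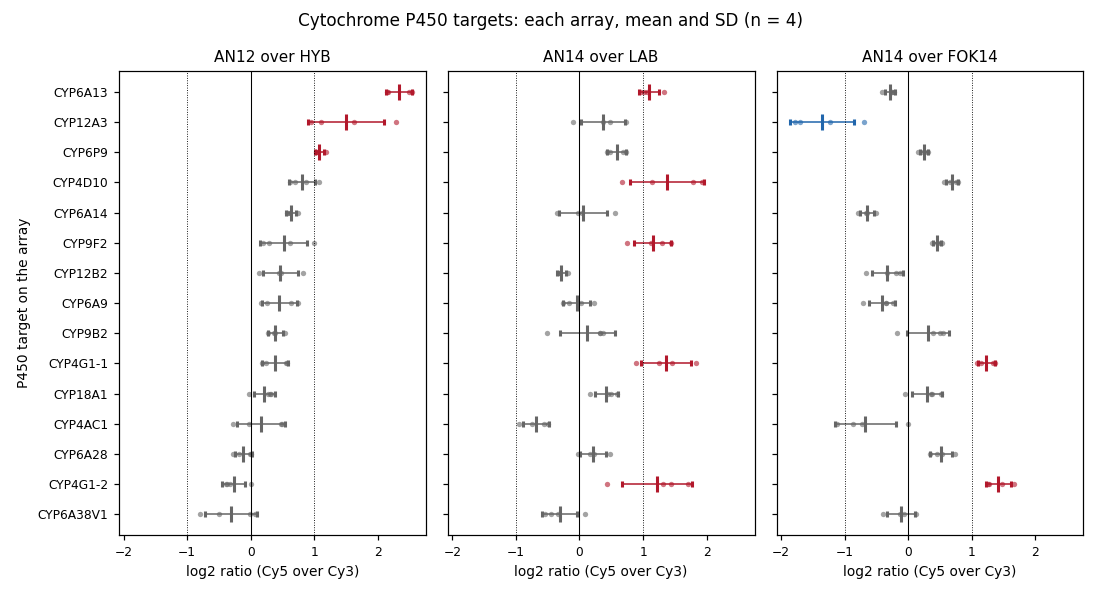
Log2 ratios of Cy5 over Cy3 of the 15 P450 targets in the 3 comparisons; dots are the 4 arrays, vertical ticks the mean, bars the SD, red and blue mark targets called higher and lower, and dotted lines mark a log2 ratio of 1 either way. CYP12A3 lay at 1.49 for AN12 over HYB and at -1.35 for AN14 over FOK14, and both CYP4G1 targets lay above 1 in the comparisons with AN14.

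The comparison of AN14 with LAB set a later collection from the treated area against the population LAB. Of the P450 targets, 5 rose in AN14. CYP4G1, which in Drosophila catalyses the last step of cuticular hydrocarbon synthesis in oenocytes, has 2 targets on the array. CYP4G1-1 was 2.57-fold higher in AN14 (1.36 ± 0.39, SD, n = 4, limma adjusted p = 3.44e-06) and CYP4G1-2 was 2.33-fold higher (1.22 ± 0.55, SD, n = 4, limma adjusted p = 4.63e-05). CYP4D10 was 2.61-fold higher (1.38 ± 0.58, SD, n = 4, limma adjusted p = 2.18e-05) and CYP6A13 2.13-fold higher (1.09 ± 0.16, SD, n = 4, limma adjusted p = 7.43e-07). CYP9F2, of a family with further insecticide-metabolising enzymes, was 2.22-fold higher (1.15 ± 0.29, SD, n = 4, limma adjusted p = 1.23e-05).

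All 5 were higher on 4 of 4 arrays. CYP6P9 at 0.58 and CYP18A1 at 0.42 passed the adjusted p with log2 ratios under 1, as did CYP4AC1 at -0.69 and CYP12B2 at -0.29, and 6 P450 targets did not pass. CYP12B2 no longer passed when any 1 of the 4 arrays was left out, and CYP18A1 lay at 0.74 with a normexp offset of 1 and at 0.99 with the scanner software's log ratio. CYP18A1 was well above background in LAB on 2 of 4 arrays. Adjusted over the list alone, 8 P450 targets passed as higher and 2 as lower. The list's median log2 ratio was 0.37 (camera p = 0.00877 with the preset correlation), and this call was lost with an estimated correlation (p = 0.0604). With median centring in place of loess CYP6A13 lay at 0.99 and CYP9F2 at 0.96, and as the mean of its probes, which ranged from 0.45 to 1.15, CYP9F2 lay at 0.80.

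Between AN14 and LAB, 1116 targets were called, 667 higher and 449 lower in AN14. Contig01742 rose with a log2 ratio of 5.77 ± 0.63 and contig12892 with 5.61 ± 0.07 (SD, n = 4), though its other probe lay at 2.54. The largest falls were those of a target named by a sequence accession, at -7.15 ± 1.12, and of rc_contig09710, at -6.69 ± 0.28. At the limma adjusted p alone 8151 targets passed, and without replicate 3, which stood apart, 1319 were called. The split between higher and lower moved to 559 and 621 with median centring, and 2044 were called with the scanner software's log ratio, 1050 higher and 994 lower.

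The comparison of AN14 with FOK14 set the treated area against a region where little insecticide was used, with both populations collected in 2014. Insecticide use and region, Crete against central Greece, cannot be told apart in it. Both CYP4G1 targets rose in AN14: CYP4G1-2 was 2.67-fold higher (1.42 ± 0.19, SD, n = 4, limma adjusted p = 1.57e-05) and CYP4G1-1 was 2.34-fold higher (1.23 ± 0.14, SD, n = 4, limma adjusted p = 7.23e-06). CYP12A3 fell, and was 2.55-fold lower in AN14 than in FOK14 (-1.35 ± 0.50, SD, n = 4, limma adjusted p = 0.000254). The CYP4G1 targets were higher and CYP12A3 lower on 4 of 4 arrays.

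A further 10 P450 targets passed the adjusted p with log2 ratios under 1 either way, among them CYP4D10 at 0.69, CYP6A28 at 0.51, CYP6A14 at -0.65 and CYP6A13 at -0.29, and 2 did not pass. Adjusted over the list alone, 8 passed as higher and 6 as lower. The list's median log2 ratio was 0.25 and its mean 0.09, and it did not pass camera's test (p = 0.487 with the preset and p = 0.583 with an estimated correlation). The median was 0.06 where both channels had to be above background on all arrays. With fry, which asks whether the members move on balance 1 way without setting them against other targets, the p was 0.0269.

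Between AN14 and FOK14, 989 targets were called, 576 higher and 413 lower in AN14. Contig00818 rose with a log2 ratio of 7.59 ± 1.46 and was well above background in FOK14 on 2 of 4 arrays, and contig01742 rose with 6.07 ± 0.20 (SD, n = 4). Contig03783 fell at -5.53 ± 0.16 and contig04877 at -4.67 ± 0.38. Other probes of contig03783 and contig00818 showed smaller ratios, down to -2.12 and 3.68. At the limma adjusted p alone 7781 targets passed, and with the scanner software's log ratio 1755 were called, 913 higher and 842 lower.

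**Figure D2:**
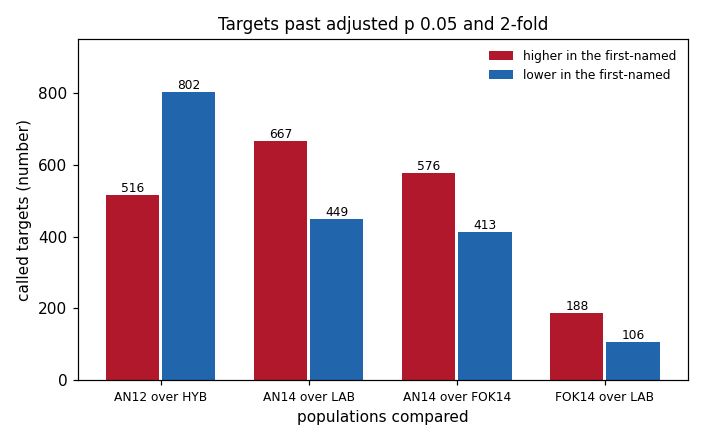
Bars give the number of targets called higher (red) and lower (blue) in the population named first, at an adjusted p below 0.05 and a log2 ratio of at least 1 either way. AN12 over HYB had 516 higher and 802 lower targets, and FOK14 over LAB had the fewest, 188 and 106.

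FOK14 and LAB were each hybridised against AN14 and were compared through it, which leaves a median SE of 0.12 on the log2 scale against 0.09 for the direct ratios. CYP12A3 was 3.30-fold higher in FOK14 than in LAB (log2 ratio 1.72, SE 0.30, limma adjusted p = 0.00412; 2.36 with the scanner software's log ratio) and CYP6A13 was 2.61-fold higher (1.39, SE 0.11, limma adjusted p = 2.01e-05). CYP6A14 at 0.70, CYP9F2 at 0.70 and CYP6P9 at 0.33 passed the adjusted p with log2 ratios under 1, and 10 P450 targets did not pass, both CYP4G1 targets among them at 0.13 and -0.20, with signs that turned when 1 array was left out. With the replicate number as a fixed block, CYP6A14 and CYP6P9 no longer passed (limma adjusted p = 0.0553 and 0.0603). Adjusted over the list alone, 6 P450 targets passed, all with higher values in FOK14. The list's median log2 ratio was 0.13 (camera p = 0.00441 with the preset correlation and p = 0.0446 with an estimated correlation). This median was 0.07 and 0.28 without replicates 1 and 3 of AN14 against LAB, 0.22 without replicate 2 of AN14 against FOK14, 0.23 with a normexp offset of 1 or with both channels above background on all arrays, and 0.36 with the scanner software's log ratio.

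In this contrast 294 targets were called, 188 higher and 106 lower in FOK14. The largest rises were those of contig04633, at 5.21 (SE 0.60), and contig12892, at 4.98 (SE 0.31). The probes of contig04633 ranged from 3.36 to 6.07, and AN14's own signal for it was 15.1 on the FOK14 arrays and 14.6 on the LAB arrays on the log2 scale. The accession-named target that fell in AN14 against LAB was not well above background in FOK14 on any array. With its dim signal raised to the floor, it was at least 416.5-fold lower there than in LAB by its ratios to AN14 (limma adjusted p = 0.000606). This bound allows for the dim signal only, not for the spread between arrays. Without the floor the log2 ratio was -9.02 (SE 1.18, 95% interval -11.59 to -6.46). The target's other probe had smaller log2 ratios, -4.66 in AN14 against LAB and -4.72 here. AN14's own signal for this target was 7.98 on the FOK14 arrays and 9.27 on the LAB arrays on the log2 scale. Contig00818 lay at -8.48 (SE 1.92, limma adjusted p = 0.0162), while another probe of contig12892 lay at 1.89. At the limma adjusted p alone 1713 targets passed, and with the scanner software's log ratio 520 were called. Over the 294 called targets the Cy3 signals, where FOK14 and LAB lay, differed by a median of 1.55 (log2, absolute) between the 2 groups of arrays and the Cy5 signals, where AN14 lay, by 0.10.

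Across comparisons, 26 targets were higher and 12 lower in the population from pyrethroid-treated orchards, AN12 or AN14, in all 3. As HYB and LAB have no description and FOK14 came from another region, these targets cannot be tied to the treatment. Given the targets that the AN14 comparisons share, chance overlap with AN12 against HYB would give 13.0 and 12.5. This expectation spreads the calls of AN12 against HYB evenly over all targets. The opposite directions exceeded it too: 269 targets higher in both AN14 comparisons were lower in AN12, against 20.2, and 28 showed the reverse, against 8.03. It therefore cannot decide whether the 26 or the 12 are in excess. Without replicates 2, 3 and 4 of AN12 against HYB the targets lower in all 3 numbered 18, 5 and 6. Without replicate 3 of AN14 against FOK14 they numbered 7. No P450 target was among these 38, since CYP6A13 was called against HYB and LAB but lay at -0.29 against FOK14, and the CYP4G1 targets were called against LAB and FOK14 but not against HYB. The total was 64 with a normexp offset of 1 and 148 with the scanner software's log ratio.

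AN14 against LAB and AN14 against FOK14 had 405 targets called higher in both, among them contig01742, CYP4G1-1 and CYP4G1-2, and 250 called lower in both. Independent lists would give 23.9 and 11.55, and 7 targets were called in opposite directions. The log2 ratios of these comparisons correlated with r = 0.741 across targets, which are not independent replicates, and their covariance was 0.260. Since AN14 is in both, unchanged populations were simulated with same-numbered arrays correlated as observed (0.354). These gave r = 0.355, a covariance of 0.0054 and no target called alike. AN14's own levels also enter both ratios, and neither this simulation, independent lists nor the choice of arrays below allows for that. The values thus do not show agreement beyond the shared population. With arrays of different numbers, replicates 1 and 2 against LAB and 3 and 4 against FOK14 gave r = 0.697 and 712 targets called alike, and the reverse choice gave r = 0.638 and 468.

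AN12 against HYB went the other way from AN14 against FOK14. Of 522 targets called in both, 474 were opposite, a share of 90.8% (exact binomial 95% interval 88.0 to 93.1), and r across targets was -0.46. The interval treats targets as independent, though they share arrays, and leaves out the spread between arrays. The correlation was below -0.3 for 12 of the 16 pairs of arrays, with a range of -0.53 to -0.23. Contig01742, for example, lay at -6.05 for AN12 over HYB and at 6.07 for AN14 over FOK14, and contig04482 at -6.61 and 4.52. Among the 48 called alike was contig00818, at 5.26 and 7.59. Directions were kept as the labels' dyes give them, since the reference populations differ. With AN14 against LAB, AN12 against HYB shared 539 called targets, 312 of them opposite and 227 alike, and r was -0.07. Contig12892 was among those alike, at 5.67 for AN12 over HYB and 5.61 for AN14 over LAB. Contig01742 was among the opposite ones, at -6.05 and 5.77. The P450 differences were tested directly: CYP12A3 differed between AN12 over HYB and AN14 over FOK14 by 2.85 (limma adjusted p = 5.29e-06), and CYP6A13 by 2.62 (limma adjusted p = 2.89e-09). With the sign of AN12 against HYB turned these would be -0.14 (limma adjusted p = 0.734) and -2.04. The first would be lost and the second would change sign, so both rest on that direction. The AN12 arrays lay on another slide than the AN14 arrays, so slide and group cannot be told apart in these differences.

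**Figure D3:**
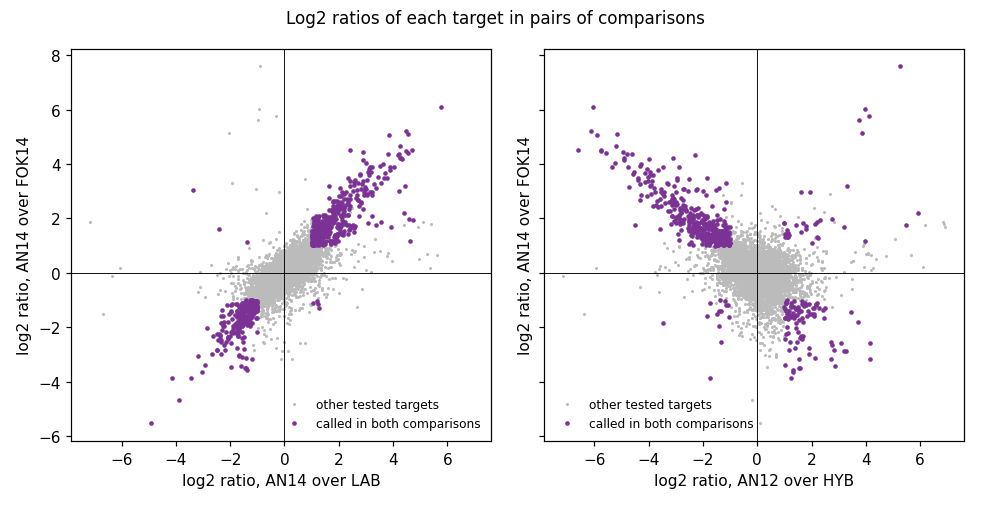
Each dot is a target with its log2 ratios in a pair of comparisons, in purple where called in both. On the left, AN14 over FOK14 is set against AN14 over LAB, where 655 targets were called alike and 7 opposite; on the right it is set against AN12 over HYB, where 48 were called alike and 474 opposite.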

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

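The tests of the 3 technical explanations for the opposite calls, and the test of a dye effect on the targets alike in all 3 comparisons, were chosen only after those results were seen. Some P450 targets whose arrays lay on opposite sides of 0 in 2 comparisons also differed by a log2 ratio of at least 1 and passed limma's test of the difference. CYP12A3 differed by 2.85 on the log2 scale between AN12 over HYB and AN14 over FOK14, CYP6A13 by 2.62 and CYP6A14 by 1.28. CYP4G1-2 was lower in AN12 over HYB than in AN14 over LAB by a log2 difference of -1.49 and than in AN14 over FOK14 by -1.68. CYP4G1-1 was above 0 in AN12 over HYB too, and its differences, in the same order, were -0.97 and -0.84. CYP6A13 differed by 1.39 between AN14 over LAB and AN14 over FOK14, which is also its ratio of FOK14 over LAB. CYP12B2 and CYP6A9 also lay on opposite sides of 0 and passed the test, with differences under 1: CYP12B2 differed by 0.75 between AN12 over HYB and AN14 over LAB, and by 0.80 and CYP6A9 by 0.87 between AN12 over HYB and AN14 over FOK14. With the sign of AN12 over HYB turned, some of the differences from AN14 over FOK14 would no longer pass. They would be -0.14 for CYP12A3, 0.02 for CYP6A14, -0.14 for CYP12B2, -0.04 for CYP6A9 and 0.51 for CYP4AC1, which was 0.84 as labelled. Those of CYP6A13 at -2.04 and CYP6P9 at -1.33 would pass with the sign reversed, as they were 2.62 and 0.83 as labelled. Those of CYP4G1-1 at -1.62, CYP4G1-2 at -1.15 and CYP6A28 at -0.40 would pass with the same sign. CYP4D10, CYP9F2, CYP9B2 and CYP18A1, whose differences from AN14 over FOK14 did not pass as labelled, would pass once turned. Turning the sign would thus remove some P450 differences, reverse others and add further ones.

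Of 75 sets of 4 values tested, 5 held an array far from the other 3, and chance gives about 1 in 20. CYP18A1 lay at -0.032 on replicate 1 of AN12 against HYB, with the others at 0.27 to 0.33. CYP4G1-2 lay at -0.0018 on replicate 3 of the same comparison, with the others at -0.38 to -0.32. In AN14 against LAB, CYP12B2 lay at -0.18 on replicate 1, with the others at -0.33 to -0.31, and CYP9B2 at -0.52 on replicate 3, with the others at 0.32 to 0.37. The median Cy5 signal of replicate 2 of AN14 against LAB was 230, with the others at 287 to 289.

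The opposite calls of AN12 against HYB and AN14 against FOK14 were set against 3 technical explanations. A dye effect of the gene would push both the same way, and 90.8% of the 522 shared calls went opposite ways. Dyes exchanged at labelling would turn the log ratios of the spike-in transcripts, yet those of 10 spike-ins correlated with r = 0.989 between the comparisons; this covers only an exchange after the spike-ins were added. An exchange of the AN12 and HYB RNA before labelling on all 4 arrays cannot be told apart from a biological difference. Neither population lies on another array. With the sign turned, 297 targets would be called alike in all 3 comparisons in place of 38, but AN14 enters both of the other comparisons. Set against AN14 over LAB alone, 227 shared calls went the same way as labelled and 312 the opposite way. A difference between the reference populations HYB and FOK14, or between collection years, stays open and was not tested.

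The 38 targets called alike in all 3 comparisons could come from a dye effect of the gene, since AN12 and AN14 were always in Cy5. A dye effect of equal size on all arrays would alone give equal ratios, and 21 of the 38 differed between comparisons by a moderated F test adjusted over the list. The test does not cover a dye effect that differs between arrays or slides, and the AN12 arrays lay on a slide of their own. For the 21 such an effect stays open. For the other 17 a dye effect of equal size stays open too, since no dyes were exchanged.

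Ratios of called targets could come from a sequence variant under a single probe, as the populations differ in origin. Of 1872 called targets with another tested probe, the other probes kept the sign and at least 50% of the log2 ratio in 85.6% (exact binomial 95% interval 83.9 to 87.1), which argues against a variant under 1 probe for most of them. This interval, too, treats targets as independent, though they share arrays. Variants under several probes, and called targets with 1 tested probe, stay open.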

How the results depend on the processing

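No called ratio of a named target and no shift of the P450 list changed direction under any alternative run, apart from AN12 against HYB with its sign turned; uncalled P450 ratios near 0, such as CYP6A14 in AN14 against LAB and CYP4G1-1 and CYP4G1-2 in FOK14 over LAB, took either sign. The turned sign of AN12 against HYB, and all settings for the opposite share and for the calls shared by the AN14 comparisons, were chosen after seeing the data, as were the separate-channel fit for counts other than that of FOK14 over LAB and, for the P450 shift, the block and the background, scaling, source, filter and probe settings. The total counts of called targets stayed within 1.5 times of their value except with the scanner software's log ratio, the deposited table, the adjusted p alone and, for all 3 comparisons, a normexp offset of 1 and the turned sign. In this order, the software's ratio, the table and the adjusted p alone gave 2074, 2074 and 9256 for AN12 against HYB, 2044, 2041 and 8151 for AN14 against LAB, 1755, 1756 and 7781 for AN14 against FOK14, 520, 521 and 1713 for FOK14 over LAB, and 148, 148 and 967 for all 3, where an offset of 1 gave 64 and the turned sign of AN12 against HYB 297. The adjusted p alone counts more by its construction; for the other settings the cause was not tested. The opposite share of AN12 against HYB and AN14 against FOK14 was 87.8% with an offset of 1, 79.95% with the software's ratio and the table, and 88.8% to 94.05% with 1 array left out. AN14 against LAB and FOK14 shared 1165 calls alike with the software's ratio and the table. The P450 shift in AN14 against LAB (0.37) had p = 0.0604 with an estimated correlation, in a range of 0.00367 to 0.0604 for camera and 1.45e-06 with fry, and that in AN14 against FOK14 (0.25) had p = 0.0269 with fry, which asks another question, against 0.347 to 0.651 for camera. With the replicate number as a block, FOK14 over LAB had 330 called targets as a fixed factor and 332 as a random one, and 291 and 294 of the 294 were among them. The named targets kept their calls, but with the fixed factor CYP6A14 and CYP6P9 no longer passed the adjusted p. Uncalled P450 ratios close to the adjusted p lost it under further settings, mostly with 1 array left out: CYP4G1-1 and CYP9B2 in AN12 against HYB, CYP12B2 in both AN14 comparisons, CYP18A1 in AN14 against FOK14, and CYP6A14, CYP6P9 and CYP9F2 in FOK14 over LAB. Of 76 ratios of named targets, 73 kept their status, called or uncalled, in all alternatives. The 76 hold all P450 ratios, most of which were uncalled, and identifiers picked for the largest ratios. An uncalled ratio that lost the adjusted p counted as kept. The 3 that changed were called ratios of CYP6P9, CYP6A13 and CYP9F2, which lost their call in 5 fits. Signal over background limits contig04635, contig06783 and contig00818, dim in a population on some arrays.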

Other observations

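Targets that rose in AN14 against both LAB and FOK14 and fell in AN12 against HYB numbered 269, with contig01742 among them. A chance overlap of AN12 against HYB with the targets that the AN14 comparisons share would give 20.2. The reverse was seen for 28, against 8.03. These expectations, too, spread calls evenly over all targets. The array carries probes for both strands of 6664 contigs, and 3220 had both strands tested. Both strands were called in the same direction for 76 of these contigs in AN12 against HYB, 50 in AN14 against LAB and 39 in AN14 against FOK14, and in opposite directions for 3, 1 and 0. For 269, 253 and 197 contigs only 1 strand was called. The log2 ratios of the strands correlated with r between 0.535 and 0.572 across contigs in these comparisons. The 13 intervals of a sequence record were among the brightest targets, with a median signal at percentile 99.8, and none was called by limma in AN12 against HYB, AN14 against LAB or AN14 against FOK14. In that order, 7, 6 and 3 passed the adjusted p alone, and 7, 6 and 4 had an unadjusted p under 0.05.

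Whether chance assignment of the arrays could give as many calls was tested by other splits. For all 3 comparisons, 1 of 100 assignments of populations to channels, the real one with 38 targets, gave as many, and the highest other gave 2. This decides nothing, since other assignments remove most calls of the single comparisons: only 1 of them left 3 lists of at least 38 targets. For each direct comparison the 4 arrays allow 8 assignments, too few for a share under 0.05: the real one gave 1318 against a highest other of 2 for AN12 against HYB, 1116 against 50 for AN14 against LAB, and 989 against 0 for AN14 against FOK14, so that 1 of 8 reached the real value each time. For FOK14 over LAB, 8 of the 35 splits of the 8 arrays part all 4 pairs of same-numbered arrays, again too few; 1 of them, the real one with 294, gave as many, and the highest other gave 0. The other splits, 24 that part 2 pairs and 3 that part none, called 0 targets.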
